A study of Mus musculus with 93 samples.

How the data were processed

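Poly(A) RNA from neural retina and posterior eyecup of female mice was sequenced, 1 library per tissue sample, in 12 groups set by tissue, genotype (wild type or Efemp1ki/ki) and age (3, 9 or 17 months). Groups and replicate numbers came from the sample titles and their characteristics. Per the labels' protocols, RNA was purified on RNeasy micro columns with DNase digestion and libraries were made with the TruSeq Stranded mRNA kit, which keeps the strand of the transcript. The submitters' processing notes name genome build GRCm38.p4. The aligner, the counting tool, the annotation version and the strand setting of the counting are not given in the sources used here.

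The authors deposited a table of estimated counts per gene, which are mostly whole numbers with some fractional parts and differ in total between libraries. They were rounded to whole numbers for the tests. The table that the authors deposited as TPM is scaled so that protein-coding genes alone sum to 1000000 in each library, so all genes together exceed that total. These values, as the authors deposited them, were therefore treated as a score and used in 1 alternative only. In each file 1 column matched no sample label and was not used here. Library totals, from 9218127 to 37475492 estimated counts, set the counting precision, and reads are not independent molecules, so replicate spread rather than counting error entered every test. No 2 libraries of a group were copies of each other, since the closest pair differed 2.42 times more than sampling noise allows (chi-square per degree of freedom).

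The tests were fixed before the data were examined. Genes were kept by filterByExpr, giving 18003 genes in the eyecup, 17240 in the retina and 19210 in both together. Normalisation used the trimmed mean of M values (TMM), and group means were fitted with edgeR 4.0.16 (robust dispersions, quasi-likelihood F test) in R 4.3.3, 1 fit per tissue over its 6 groups. Genotype was compared at each age and as the mean of the 3 ages, age as 17 against 3 months within each genotype, and the change of the genotype difference from 3 to 17 months as an interaction. A joint fit of all 12 groups tested whether the genotype difference differed between tissues. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic, and levels are TMM-scaled CPM with SD over libraries. Permutation and Fisher's exact tests were 2-sided.

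Named genes followed a rule. Efemp1 and Cfb were always given. For each comparison, among called genes with a mean log2 CPM of at least 0 and no predicted-gene name, the 10 smallest p-values in each direction with an absolute log2 fold change of at least 0.5 and the 3 largest fold changes in each direction were eligible. Where fewer than 10 genes passed, every one was. In each list described, the 4 members with the smallest p were eligible, as was every called complement component or regulator, and the 10 smallest p-values were eligible for the tests of a difference between differences. C4a, set beside C4b, and the marker gene Acta1, given as a level, lie outside this rule, C4a having been chosen after its values were seen.

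A set of 50 gene lists (pathways, cell types and contaminating tissues) was fixed beforehand, and those with at least 4 tested members, 49 in the eyecup and 45 in the retina, were tested with camera in limma 3.58.1 on voom values. The preset correlation between genes was 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and the test was repeated with a correlation estimated per list. No list passed with an estimated correlation in any of the 8 genotype comparisons. Member counts are given over all genes and adjusted over the list alone.

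Alternatives planned beforehand were edgeR with RLE size factors, no filter beyond 1 read, only the 2 groups compared, the replicate number as a block, limma voom with quality weights, limma on log2(TPM + 1) with a pseudocount of 1, DESeq2 1.42.0, surrogate variables from sva 3.50.0 (4 in the eyecup, 9 in the retina), covariates for marker lists of neighbouring tissue (skeletal muscle, rods and ocular surface epithelium in the eyecup, pigment epithelium, lens and rods in the retina), and leaving out libraries that stood apart from their group by more than 3 scaled median absolute deviations (1 eyecup, 2 retinas). Chosen after seeing the data were GC offsets per library, from a spline with 5 degrees of freedom on the GC content of the longest GENCODE transcript of a gene (99.8% of genes matched), their combinations with the covariates and the block, and leaving out libraries with an extreme GC trend by the same limit (2 eyecups, 4 retinas). Permutation tests were stratified by age or exact, and 40 splits of the same libraries, the real one included, were run per comparison.

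The fits were tested on simulated counts with known changes at 3 months. In the eyecup (17773 genes) edgeR recovered 38.8, 71.6 and 90.9% of genes changed 1.5, 2 and 4 times, with 4.29% false calls. In the retina (17134 genes) it recovered 86.6, 95.5 and 98.5%, with 6.03% false calls. DESeq2 had 13.0% and 8.57% false calls, respectively. Real libraries may differ, as a split of 17-month eyecups called 5341 genes.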

Results

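Messenger RNA was sequenced from the neural retina and from the posterior eyecup, which the series describes as the whole eye without lens and retina, of female mice. The mice were wild type or Efemp1ki/ki, a homozygous knock-in of Efemp1 that serves as a model of Doyne honeycomb retinal dystrophy, an inherited macular disease with deposits under the retinal pigment epithelium. Tissue was taken at 3, 9 and 17 months of age, giving 12 groups and 93 libraries. Each group had 8 libraries, except wild-type eyecups at 3 months with 6 and Efemp1ki/ki eyecups at 17 months with 7. Library totals ran from 14236127 to 35297627 estimated counts in the eyecup (median 19982911, 45 libraries). Those of the retina ran from 9218127 to 37475492 (median 16813523, 48 libraries). Acta1, encoding skeletal muscle actin, ranged from 388 to 4477 CPM, the count scaled to the library's total, in eyecups and from 0.284 to 1.98 CPM in retinas. In wild-type eyecups at 3 months the corneal and conjunctival epithelium genes averaged 10.3 log2 CPM and the retinal pigment epithelium genes 6.09, so the eyecup libraries held transcripts typical of the ocular surface. Expression varied more between eyecups than between retinas of one group, with a common biological coefficient of variation of 0.309 against 0.0963. The labels did not say whether each library came from a separate mouse, so the p-values measure the spread between these libraries.

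Efemp1 (ENSMUSG00000020467.15, chromosome 11, 28853204 to 28926743 in GRCm38), which encodes the extracellular matrix protein fibulin-3, was transcribed at similar levels in both genotypes. Eyecup libraries held 147 to 305 TMM-scaled CPM in wild type and 138 to 301 in Efemp1ki/ki. In retina libraries the ranges were 46.6 to 78.1 and 48.2 to 84.7 CPM. At 3, 9 and 17 months the Efemp1ki/ki eyecup means were 235 ± 43.5, 246 ± 38.9 and 208 ± 39.5 CPM (SD, n = 8, 8 and 7), against 255 ± 39.5, 252 ± 48.4 and 217 ± 47.9 in wild type (n = 6, 8 and 8). No genotype difference in Efemp1 passed at any age in either tissue (smallest adjusted p = 0.650, edgeR quasi-likelihood test). A knock-in need not alter the amount of transcript, so these values did not check the genotype labels. Cfb (ENSMUSG00000090231.10, chromosome 17, 34856374 to 34862518), encoding complement factor B of the alternative pathway, likewise showed no genotype difference past the threshold. In Efemp1ki/ki eyecups it measured 10.9 ± 2.82, 18.9 ± 7.70 and 20.8 ± 5.53 CPM at 3, 9 and 17 months, against 10.3 ± 0.890, 14.1 ± 3.77 and 18.3 ± 7.04 in wild type. Cfb rose from 3 to 17 months in eyecups of both genotypes, with log2 fold changes of 0.82 ± 0.23 (SE) in wild type and 0.93 ± 0.22 in Efemp1ki/ki. Their adjusted p-values were 0.0286 and 0.00856, respectively.

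The comparison of genotypes asks what the mutant fibulin-3 changes in each tissue as the mice age. In eyecups at 3 months, 553 of 18003 genes differed, 84 higher and 469 lower in Efemp1ki/ki. Plagl1 (ENSMUSG00000019817.18, chromosome 10, 13060504 to 13131694), an imprinted zinc finger transcription factor, fell from 17.3 ± 2.82 to 7.28 ± 1.62 CPM (SD, n = 6 and 8; log2 fold change -1.25 ± 0.20, adjusted p = 0.00183). Slc18a2, the vesicular monoamine transporter gene, fell by 1.07 on the log2 scale, Gulp1, an engulfment adaptor gene, by 1.14, Dfna5, which encodes the pore-forming protein gasdermin E, by 0.79, and Marcks, a substrate of protein kinase C, by 0.89. Tbc1d19, Zfp943, Rmi1, Vbp1 and Cbx3 also fell, with log2 fold changes from -1.09 ± 0.20 to -0.53 ± 0.10, though Cbx3 turned to 0.0273 on the log2(TPM + 1) scale. The larger decreases of Zfp968 (-3.34 ± 0.92), Znf41-ps (-2.15 ± 0.42) and Cxcl1 (-1.99 ± 0.58) came from genes under 3 CPM, and Znf41-ps is a pseudogene whose reads are uncertain. The value for Cxcl1 rested in part on wild-type library 6, at 3.46 log2 CPM against 0.58 in the next. Among genes that rose were Nr4a1, an activity-induced nuclear receptor (0.83 ± 0.24, adjusted p = 0.0429), Papln, encoding the matrix protein papilin (0.52 ± 0.14, adjusted p = 0.0355), and the ribosomal protein gene Rps23 (0.56 ± 0.15, adjusted p = 0.0369), which has processed copies elsewhere in the genome. Of 18 immediate early genes, 1 rose over all genes and 2 adjusted over the list alone (median log2 fold change 0.40). Camera gave adjusted p = 7.16e-05 for this list, and adjusted p = 0.999 with an estimated correlation. None of the 9 mitochondrially encoded genes passed over all genes, yet 6 were lower adjusted over the list alone (median -0.75). As a list they had camera adjusted p = 7.22e-06, and adjusted p = 0.999 with an estimated correlation. The complement component list did not pass (median 0.23; camera adjusted p = 0.0951). Genes that fell had a median transcript GC content of 40.03% and genes that rose 56.0%, against 49.7% over all genes, and fold change rose with GC content across genes (Spearman correlation = 0.698, genes not being independent). The GC trend of a library, its log2 deviation per 10 percentage points of GC, averaged 0.228 ± 0.276 in 8 Efemp1ki/ki eyecups and -0.0737 ± 0.0255 in 6 wild-type ones (exact permutation p = 0.00366, adjusted p = 0.0220 over 6 comparisons). With a GC correction chosen after seeing the data, 17 genes passed, 7 of them higher, 386 passed with that correction and composition covariates together, and without Efemp1ki/ki libraries 3 and 4, which had the steepest GC trends, 14 passed. Plagl1 passed in all 14 alternative settings run.

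**Figure D1:**
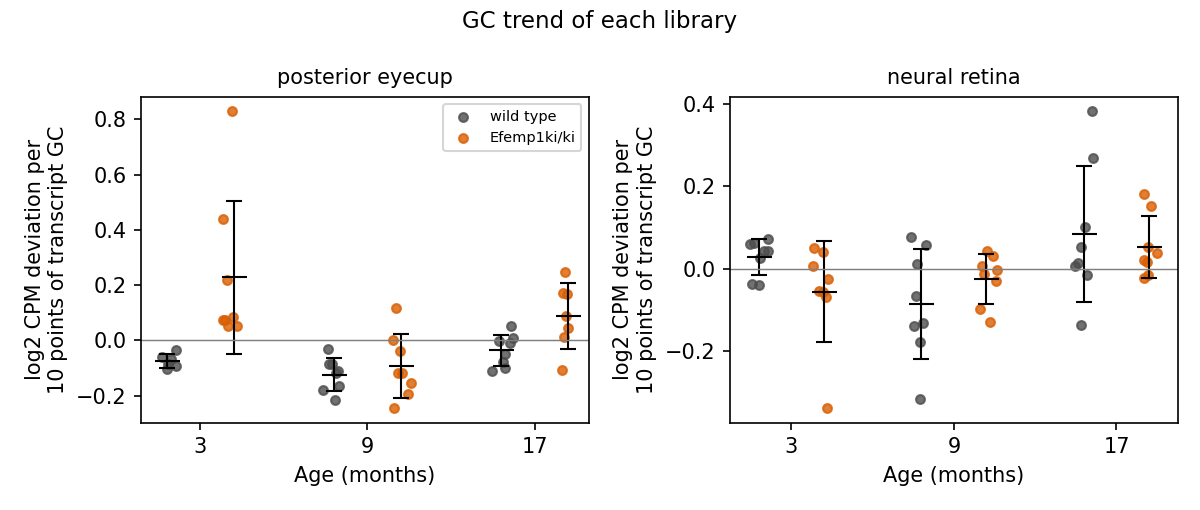
GC trend of each library, as log2 CPM deviation per 10 percentage points of transcript GC content, by age in months, 1 point per library, grey for wild type and orange for Efemp1ki/ki, with bars for the mean and SD of each group. Efemp1ki/ki eyecup libraries 3 and 4 at 3 months lie at 0.439 and 0.83, above the 6 wild-type ones, which average -0.0737.

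At 9 months the eyecups differed in 1 gene. Alb, which encodes the plasma protein albumin, measured 0.0379 ± 0.0462 CPM in Efemp1ki/ki and 2.96 ± 4.30 CPM in wild type (SD, n = 8 each; log2 fold change -6.13 ± 1.09, adjusted p = 0.0267), a low level with a wide spread. At an unadjusted p under 0.05 there were 249 of the 18003 genes, 1.38%, where chance alone gives about 5%. Of 13 retinal pigment epithelium markers none passed (median log2 fold change -0.39). Their library means differed by -0.279 (exact permutation p = 0.190, adjusted p = 0.490). The list had camera adjusted p = 4.12e-08, and adjusted p = 0.373 with an estimated correlation. Of 18 immediate early genes 0 passed by edgeR, over all genes or adjusted over the list alone (median 0.26). Their list had camera adjusted p = 1.73e-08, and adjusted p = 0.373 with an estimated correlation. DESeq2 and limma voom with quality weights called 0 genes.

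At 17 months 11 genes differed between eyecups, 8 higher and 3 lower in Efemp1ki/ki. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), the gene of the inflammatory cytokine tumour necrosis factor, rose from 2.68 ± 1.20 to 12.0 ± 11.0 CPM (SD, n = 8 and 7; log2 fold change 2.16 ± 0.39, adjusted p = 0.0145). Zc3h12a, encoding an endoribonuclease that degrades inflammatory transcripts, rose as well (1.22 ± 0.25, adjusted p = 0.0450), as did Smpdl3b, a sphingomyelin phosphodiesterase-like gene (0.99 ± 0.19, adjusted p = 0.0317), and the kallikrein gene Klk10 (1.63 ± 0.32, adjusted p = 0.0366). The phosphatase gene Cdc14a (-0.38 ± 0.08), Dfna5 (-0.63 ± 0.13) and the claudin-like gene Cldn34c1 (-1.54 ± 0.33) fell, each with adjusted p = 0.0450. Dfna5 was thus lower at both 3 and 17 months, and 3 of the 11 genes were among those called in the same direction at 3 months. Tnf was the 1 member of 20 in the list of NF-kB and acute inflammation genes that rose over all genes, and 8 did adjusted over the list alone. Lcn2, encoding lipocalin 2, had a log2 fold change of 2.10 ± 0.53 without passing over all genes, and the chemokine gene Cxcl2 one of 2.21 ± 0.64. The list had camera adjusted p = 1.11e-05, with adjusted p = 0.766 with an estimated correlation. No unfolded protein response gene of 26 passed over all genes, whereas 13 rose adjusted over the list alone, among them the endoplasmic reticulum chaperone gene Hyou1 (0.32 ± 0.08), Creld2 (0.42 ± 0.11) and Sdf2l1 (0.53 ± 0.14). Their list test gave camera adjusted p = 3.62e-10, and adjusted p = 0.430 with an estimated correlation. Similarly, 13 of 18 immediate early genes rose adjusted over the list alone and 0 over all genes by edgeR, with Egr1 at 1.35 ± 0.37 and Ier3 at 0.73 ± 0.19. Efemp1ki/ki library 5 stood apart here, with a list mean of 5.86 against 4.93 log2 CPM in the next library, Egr1 at 347 against 123 CPM and Fos at 131 against 55.5. Over the whole list there was camera adjusted p = 1.83e-09, and adjusted p = 0.430 with an estimated correlation. Over the whole transcriptome 1803 genes had an unadjusted p under 0.05, while DESeq2 called 52 genes and limma voom with quality weights 478. By contrast, 1 gene passed with the replicate number as a block, and 0 did with only the 2 groups compared or on the log2(TPM + 1) scale. Without Efemp1ki/ki library 4, which stood apart from its group in all expressed genes, 3 genes passed, and with the GC correction 0 did.

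Averaged over the 3 ages, 807 genes differed between eyecups of the genotypes, 201 higher and 606 lower in Efemp1ki/ki. Egr1, a zinc finger transcription factor induced within minutes of stimulation, was higher by 1.15 ± 0.22 on the log2 scale (adjusted p = 0.00179) and lay above the wild-type median in 23 of 23 knock-in libraries. With Fosb (1.14 ± 0.26), Fos (0.66 ± 0.16), Nr4a1 (0.64 ± 0.13) and Atf3 (0.57 ± 0.13) it belonged to 11 of 18 immediate early genes that rose over all genes, 13 adjusted over the list alone. Camera gave adjusted p = 2.21e-10 for this list, and adjusted p = 0.554 with an estimated correlation. Epidermal differentiation genes Ovol1 (0.54 ± 0.14) and Kprp (0.82 ± 0.22) rose, as did the zinc finger gene Zxda (0.89 ± 0.22), the non-coding Hopxos (0.51 ± 0.12), which overlaps Hopx, and the pseudogene Eif4a-ps4 (0.54 ± 0.12), whose reads are uncertain. The decreases were led by Gulp1 (-0.79 ± 0.11, adjusted p = 6.13e-05), Dfna5 (-0.55 ± 0.08, adjusted p = 6.13e-05), Plagl1 (-0.77 ± 0.11), Marcks (-0.58 ± 0.09), the polycomb gene Bmi1 (-0.56 ± 0.09), Tmem56 (-0.70 ± 0.11), the integrin gene Itgb8 (-0.73 ± 0.13), Sh3bgrl (-0.74 ± 0.13), Vbp1 (-0.53 ± 0.09) and Igip (-0.52 ± 0.09). Cldn34c1 (-0.96 ± 0.18), Zfp968 (-1.85 ± 0.49) and Znf41-ps (-1.23 ± 0.23) fell further at low expression. Of 13 retinal pigment epithelium genes, 2 fell, namely the visual cycle genes Lrat (-0.61 ± 0.16, adjusted p = 0.0179) and Rpe65 (-0.48 ± 0.14, adjusted p = 0.0474), and the same number did adjusted over the list alone. As a list they had camera adjusted p = 0.00477, and adjusted p = 0.969 with an estimated correlation. Among 12 melanocyte genes, Slc24a5 fell (-0.47 ± 0.12, adjusted p = 0.0208), with 7 lower adjusted over the list alone. The list as a whole had camera adjusted p = 0.00268, and adjusted p = 0.969 with an estimated correlation. Mitochondrially encoded genes fell in 3 of 9 cases, mt-Co3 by 0.91 on the log2 scale, and in 6 adjusted over the list alone. Tested together, these genes had camera adjusted p = 8.89e-06, and adjusted p = 0.969 with an estimated correlation. The unfolded protein response list had 5 of 26 members higher over all genes and 12 adjusted over the list alone. Their list test gave camera adjusted p = 2.63e-05, and adjusted p = 0.969 with an estimated correlation. Fold change again rose with GC content across genes (Spearman correlation = 0.594), and 153 genes passed with the GC correction, 61 of them higher. On the log2(TPM + 1) scale 34 genes passed, 17 of them higher, and Igip changed sign there.

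In the neural retina at 3 months, 316 of 17240 genes differed, 166 higher and 150 lower in Efemp1ki/ki. The salt-inducible kinase gene Sik1 (ENSMUSG00000024042.6, chromosome 17, 31844248 to 31855792) rose from 10.4 ± 1.73 to 16.9 ± 1.86 CPM (SD, n = 8 each; log2 fold change 0.71 ± 0.11, adjusted p = 0.000943), Nr4a1 by 0.82 ± 0.14, Fos by 1.22 ± 0.23, Egr1 by 1.78 ± 0.38 and the phosphatase gene Dusp1 by 0.59 ± 0.13. The death receptor gene Tnfrsf25 (1.11 ± 0.19), the stanniocalcin gene Stc1 (0.67 ± 0.14), Gfy (0.78 ± 0.17), the antisense transcript Srrm4os (0.68 ± 0.15) and the pseudogene Kpna2-ps (0.58 ± 0.10), the last of uncertain read origin, rose too. Hes5, a Notch target expressed in Mueller glia, fell (-0.52 ± 0.11, adjusted p = 0.0107), and so did Wnt16 (-0.66 ± 0.17), the fucosyltransferase gene Fut4 (-0.54 ± 0.14), the endothelial transcription factor gene Sox18 (-0.58 ± 0.16), the E-cadherin gene Cdh1 (-0.95 ± 0.26) and Fam46b (-0.81 ± 0.23). 4 of 17 listed immediate early genes rose, both over all genes and adjusted over the list alone. Over the whole list there was camera adjusted p = 1.94e-05, and adjusted p = 0.700 with an estimated correlation. Of 13 Mueller glia genes 2 fell, Hes1 (-0.41 ± 0.10) and Gpr37 (-0.15 ± 0.04), and 7 did adjusted over the list alone. Camera gave adjusted p = 0.000196 for this list, and adjusted p = 0.700 with an estimated correlation. Rod photoreceptor genes moved little, with a median log2 fold change of -0.10 and 0 of 19 past over all genes by edgeR, 5 lower adjusted over the list alone. As a list they had camera adjusted p = 0.000621, and adjusted p = 0.750 with an estimated correlation. Nuclear genes of oxidative phosphorylation had a median of -0.12, with 0 of 41 past over all genes and 9 lower adjusted over the list alone. The list as a whole had camera adjusted p = 1.55e-09, and adjusted p = 0.700 with an estimated correlation. Markers of neighbouring tissues varied between libraries. The median log2 fold change of 10 lens crystallins was 4.64, with 0 past over all genes by edgeR and 10 adjusted over the list alone, and adjusted p = 0.814 with an estimated correlation. Their mean in a library was 0.540 ± 2.69 log2 CPM in Efemp1ki/ki and -1.56 ± 1.08 in wild type (SD, n = 8 each; exact permutation p = 0.0508, adjusted p = 0.230). Corneal and conjunctival keratinocyte genes had a median of -1.64, with 8 of 12 lower adjusted over the list alone and adjusted p = 0.784 with an estimated correlation. Their library means differed by -1.14 (exact permutation p = 0.0274, adjusted p = 0.194). Retinal pigment epithelium genes had a median of -0.49. Tested together, these genes had camera adjusted p = 0.0126, and adjusted p = 0.814 with an estimated correlation. With covariates for pigment epithelium, lens and rod marker lists in the model 0 genes passed with edgeR and 1375 had an unadjusted p under 0.05, against 3394 in the fit without them. DESeq2 called 594 genes and limma voom with quality weights 1927, both without these covariates. On the log2(TPM + 1) scale 648 genes passed, of which 89.5% were higher, against 52.5% of the 316.

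At 9 months 0 genes passed in the retina with edgeR, with 1047 at an unadjusted p under 0.05. DESeq2, limma voom and limma on log2(TPM + 1) also called 0, and surrogate variables 2. Interferon response genes had the lowest list p (median log2 fold change 0.63; 12 of 27 higher adjusted over the list alone). Camera adjusted p was 8.61e-14, and 0.681 with an estimated correlation. Library means differed by 0.423 (exact permutation p = 0.0420, adjusted p = 0.230). Examples were Gbp3 (0.83 ± 0.27) and Xaf1 (0.66 ± 0.21), each with adjusted p = 0.796 over all genes. Antigen presentation genes of MHC class I had a median of 0.24 (camera adjusted p = 6.91e-08, adjusted p = 0.404 with an estimated correlation). Lens genes had one of 4.41, 10 of 10 higher adjusted over the list alone (adjusted p = 0.693 with an estimated correlation). Their library means differed by 1.54 (exact permutation p = 0.150, adjusted p = 0.413). Efemp1ki/ki library 6 stood at 5.84 log2 CPM, the next at 1.24.

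At 17 months 70 genes differed in the retina, 31 higher and 39 lower in Efemp1ki/ki. C4b (ENSMUSG00000073418.4, chromosome 17, 34728380 to 34743882), which encodes complement component C4 of the classical and lectin pathways, rose from 37.8 ± 4.91 to 84.7 ± 23.8 CPM (SD, n = 8 each), a log2 fold change of 1.17 ± 0.16 with adjusted p = 0.000147. All 8 knock-in libraries lay above the highest wild-type library. C3 (ENSMUSG00000024164.15, chromosome 17, 57203970 to 57228136), the central complement component, rose from 5.67 ± 0.974 to 10.5 ± 4.19 CPM (0.90 ± 0.19, adjusted p = 0.0415), and passed in 7 of 14 alternative settings, which gave adjusted p-values from 0.00703 to 0.263. C4b is nearly identical to C4a, whose log2 fold change was 0.32 ± 0.13 (adjusted p = 0.225), so reads of these 2 genes are uncertain.

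**Figure D2:**
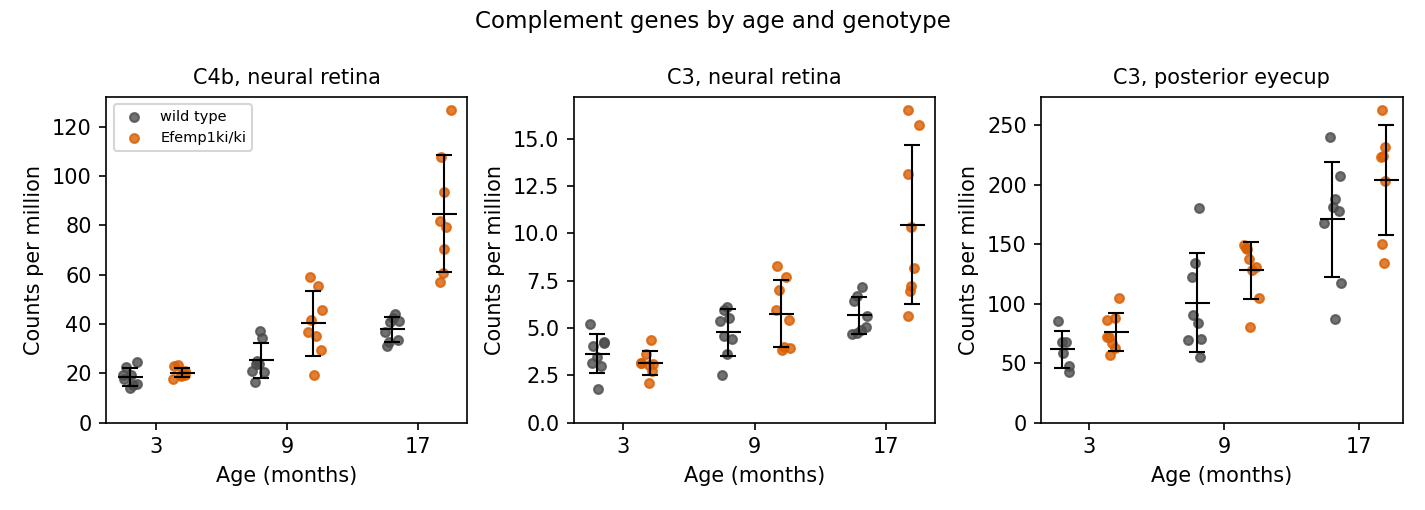
C4b and C3 in CPM by age in months, 1 point per library, grey for wild type and orange for Efemp1ki/ki, with bars for the mean and SD of each group. At 17 months the 8 Efemp1ki/ki retinas average 84.7 CPM of C4b against 37.8 in wild type, while eyecup C3 rises with age in both genotypes.

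Of 12 complement component genes 2 rose over all genes and 8 adjusted over the list alone, including C1s1 (0.43 ± 0.14). Over the whole list there was camera adjusted p = 1.79e-05, and adjusted p = 0.203 with an estimated correlation. The reactive glia list held C4b as its 1 member past the threshold, both over all genes and adjusted over the list alone, with Gfap at 0.36 ± 0.14. Camera gave adjusted p = 2.21e-05 for this list, and adjusted p = 0.203 with an estimated correlation. Interferon response genes had 0 of 27 past over all genes by edgeR but 18 higher adjusted over the list alone, such as the antiviral genes Mx2 (1.5 ± 0.41) and Rsad2 (1.54 ± 0.44). Camera adjusted p was 8.06e-12, and 0.406 with an estimated correlation. Library means differed by 0.475 (exact permutation p = 0.0648, adjusted p = 0.267). The interferon-induced GTPase gene Ifi47, outside that list, rose (1.37 ± 0.33, adjusted p = 0.0415). Other increases were Aebp1, encoding a collagen-binding matrix protein (0.63 ± 0.13), the protease gene Bace2 (1.03 ± 0.25), Nr4a1 (0.58 ± 0.14) and the basement membrane collagen gene Col4a5 (0.30 ± 0.07). Prss56, a serine protease gene of Mueller glia linked to eye size, fell from 45.3 ± 18.2 to 22.04 ± 3.89 CPM (-1.03 ± 0.24, adjusted p = 0.0415), and B3gnt9 (-0.43 ± 0.10) and Tcerg1l (-0.47 ± 0.12) also fell. Retinal ganglion cell genes were lower adjusted over the list alone in 6 of 12 cases and in 0 over all genes by edgeR, with Thy1 at -0.21 ± 0.06. The list as a whole had camera adjusted p = 1.48e-05, and adjusted p = 0.228 with an estimated correlation. Amacrine cell genes did so in 4 of 11. Tested together, these genes had camera adjusted p = 3.08e-05, and adjusted p = 0.203 with an estimated correlation. Without wild-type library 2, which stood apart, and Efemp1ki/ki library 5 at 3 months, 1 gene passed, C4b. The fits with DESeq2, limma voom with quality weights and limma on log2(TPM + 1) called 272, 1 and 682 genes, the last with 84.9% higher against 44.3% of the 70, and C4b passed in all 14 alternative settings run.

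Averaged over the ages, 903 genes differed in the retina, 439 higher and 464 lower in Efemp1ki/ki. C4b (0.66 ± 0.10, adjusted p = 0.000216), Nr4a1 (0.52 ± 0.08), Fos (0.73 ± 0.14), Egr1 (1.09 ± 0.22) and Tnfrsf25 (0.52 ± 0.10) rose, and Tcerg1l (-0.31 ± 0.07), Wnt16 (-0.40 ± 0.09) and the LIM domain gene Lmcd1 (-0.31 ± 0.09) fell. The 4 immediate early genes past the threshold, of 17, became 5 adjusted over the list alone. Their list test gave camera adjusted p = 0.000200, and adjusted p = 0.484 with an estimated correlation. The largest fold changes belonged to lens crystallins, with Cryaa at 5.70 ± 1.12, Crybb2 at 5.32 ± 1.19, Crygs at 4.95 ± 1.20, Cryba2 at 4.47 ± 0.98 and Cryba1 at 4.03 ± 0.94, and 9 of 10 lens genes rose over all genes. Levels varied widely between libraries: Cryaa averaged 48.0 ± 130 CPM (SD, n = 24) in Efemp1ki/ki and 1.32 ± 4.31 CPM in wild type (n = 24), with 22 knock-in libraries above the wild-type median. With surrogate variables Cryaa, Cryba2 and Cryba1 changed sign.

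**Figure D3:**
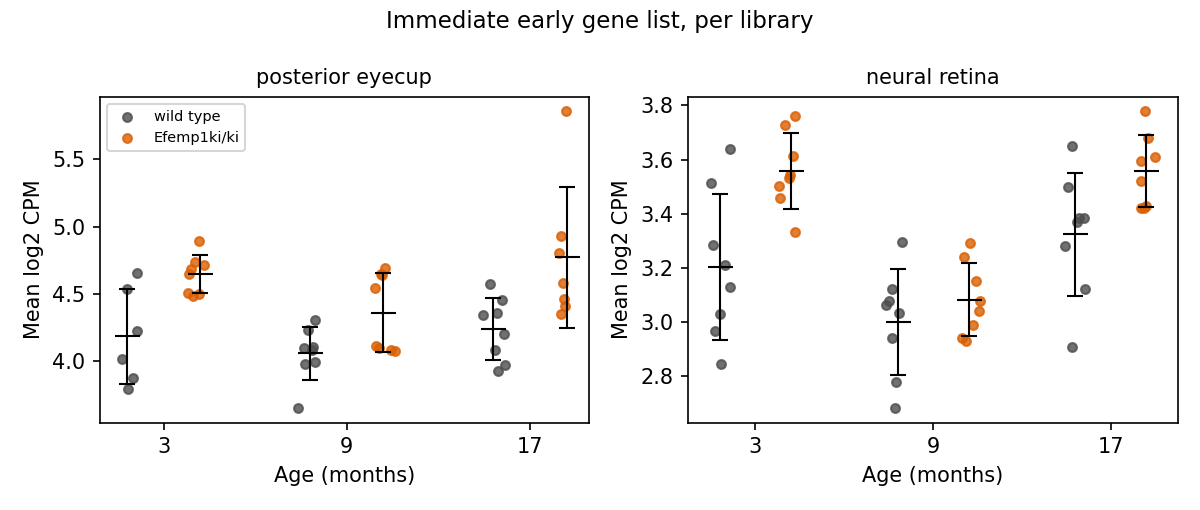
Mean log2 CPM of the immediate early gene list by age in months, 1 point per library, grey for wild type and orange for Efemp1ki/ki, with bars for the mean and SD of each group. Averages at 3 months are 4.65 against 4.18 in eyecups and 3.56 against 3.20 in retinas.

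Ganglion cell genes fell in 4 of 12 cases over all genes and 8 adjusted over the list alone, among them Thy1 (-0.12 ± 0.03), Rbpms (-0.11 ± 0.03) and Sncg (-0.20 ± 0.06). Over the whole list there was camera adjusted p = 8.37e-06, and adjusted p = 0.268 with an estimated correlation. For Mueller glia the counts were 4 and 6 of 13, led by Gpr37 (-0.13 ± 0.02) and Hes1 (-0.21 ± 0.06; camera adjusted p = 4.88e-05, adjusted p = 0.268 with an estimated correlation), and for bipolar cells 4 and 4 of 14, with Vsx1 at -0.12 ± 0.03. Camera gave adjusted p = 0.00316 for this list, and adjusted p = 0.364 with an estimated correlation. Basement membrane genes rose in 3 of 21 cases, namely Col4a5 (0.18 ± 0.04), the agrin gene Agrn (0.14 ± 0.03) and Col4a4 (0.13 ± 0.04), and in 7 adjusted over the list alone. As a list they had camera adjusted p = 2.92e-05, and adjusted p = 0.368 with an estimated correlation. With covariates for cell composition 252 genes passed, and with surrogate variables 13. On the log2(TPM + 1) scale 2008 genes passed, 83.5% of them higher, against 48.6% of the 903.

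Whether the knock-in acted differently in the tissues was tested in a joint fit, in which 620 of 19210 genes had a genotype difference that differed between eyecup and retina, 157 more positive and 463 more negative in the eyecup. The fit treated all libraries as independent, since the labels do not say whether a number marks the same mouse in both tissues. Log2 fold changes are given for the eyecup and then the retina. Plagl1 had log2 fold changes of -0.78 ± 0.10 and 0.02 ± 0.09 (adjusted p = 0.000599 for the difference), and Dfna5 had -0.57 ± 0.07 and -0.01 ± 0.06. Gulp1 (-0.80 ± 0.10 and -0.05 ± 0.09), Tmem56 (-0.72 ± 0.10 and 0.02 ± 0.09) and Itgb8 (-0.74 ± 0.11 and 0.07 ± 0.10) showed the same order, as did Ccdc141, Rmi1 and 1600012H06Rik. Prpf38b did too, but turned to 0.0623 with the GC correction. Trib1, a pseudokinase gene, was the 1 gene of the 10 with the smallest p that was more positive in the eyecup (0.26 ± 0.05 and -0.13 ± 0.05). For Efemp1 and Cfb no difference between tissues passed (adjusted p = 0.796 and 0.772). With the GC correction 51 genes passed, 52.9% of them more positive in the eyecup, and with RLE size factors in edgeR 715 passed, 50.2% of them more positive, against 25.3% of the 620.

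Ageing from 3 to 17 months changed 1059 eyecup genes in wild type, 491 upward and 568 downward, and 643 in Efemp1ki/ki, 469 upward and 174 downward. Log2 fold changes given in pairs are those of wild type and then Efemp1ki/ki. Lyz2 (ENSMUSG00000069516.7, chromosome 10, 117277334 to 117282274), encoding lysozyme, rose from 99.7 ± 19.0 to 348 ± 82.4 CPM in wild type (SD, n = 6 and 8) and from 102 ± 32.1 to 393 ± 92.4 in Efemp1ki/ki (n = 8 and 7). The log2 fold changes of Cst7, the cystatin F gene, were 2.84 ± 0.35 and 3.60 ± 0.33, and those of Itgax, encoding integrin CD11c, 1.80 ± 0.20 and 1.96 ± 0.18. Mpeg1, encoding perforin-2 (1.46 ± 0.17 and 1.64 ± 0.16), the NADPH oxidase gene Cybb (1.49 ± 0.18 and 1.67 ± 0.17), the osteoclast proton pump gene Atp6v0d2 (2.26 ± 0.28 and 2.16 ± 0.25) and Lilrb4a (1.47 ± 0.19 and 1.72 ± 0.18) rose similarly. Itgb2 (1.5 ± 0.19), the B-cell lectin gene Cd22 (1.62 ± 0.22) and the cholesterol exporter gene Abca1 (0.64 ± 0.09) were among the leading increases in wild type, and Vcam1 (1.36 ± 0.14), Clec7a (2.40 ± 0.25) and the macrophage elastase gene Mmp12 (1.94 ± 0.22) in Efemp1ki/ki. Very large fold changes at low or uneven expression belonged to Reg3g (8.62 ± 1.72) and the mucin gene Muc5b (4.93 ± 1.07) in Efemp1ki/ki, and to immunoglobulin genes such as Igha (3.06 ± 0.66) in wild type, which like Mup11 lie in families whose reads are uncertain. Complement component genes rose in 6 of 16 cases in wild type and in 6 in Efemp1ki/ki, 7 and 7 adjusted over the list alone. They were C3 (1.47 ± 0.22 and 1.42 ± 0.20), C1qa (0.99 ± 0.15 and 0.98 ± 0.14), C1qb, C1qc, C2 (0.65 ± 0.19 and 0.77 ± 0.18) and Cfb (camera adjusted p = 5.38e-07 and 4.49e-05; adjusted p = 0.371 and 0.456 with an estimated correlation). Of 16 microglia and macrophage genes 9 rose in wild type and 11 in Efemp1ki/ki, 10 and 11 adjusted over the list alone, including Ctss (1.16 ± 0.17 and 1.17 ± 0.15) and Trem2 (1.38 ± 0.21 and 1.47 ± 0.19; adjusted p = 0.307 and 0.0625 with an estimated correlation). T and natural killer cell genes rose in 4 of 11 cases in Efemp1ki/ki, with Cd3e at 1.97 ± 0.34, and in 1 in wild type (8 and 3 adjusted over the list alone; adjusted p = 0.0338 and 0.392 with an estimated correlation). Collagens and small proteoglycans fell in 6 and 7 of 22 cases, 12 in each genotype adjusted over the list alone, with Col1a1 at -0.96 ± 0.21 and -1.15 ± 0.21, Col12a1 at -1.05 ± 0.16 and -0.89 ± 0.16 and the corneal keratocan gene Kera at -1.64 ± 0.29 and -1.45 ± 0.28 (adjusted p = 0.392 and 0.327 with an estimated correlation). Proliferation genes fell in 15 of 16 cases in wild type, such as Mki67 (-0.91 ± 0.21), with 16 adjusted over the list alone (camera adjusted p = 1.52e-13, adjusted p = 0.371 with an estimated correlation), and in 0 in Efemp1ki/ki by edgeR. For the difference between genotypes the list had camera adjusted p = 4.22e-10 and adjusted p = 0.996 with an estimated correlation. Cholesterol synthesis genes fell in 9 of 23 in wild type, with 18 adjusted over the list alone (adjusted p = 0.392 with an estimated correlation), and in 0 in Efemp1ki/ki by edgeR. The genotypes differed in this list with camera adjusted p = 0.00733, and adjusted p = 0.996 with an estimated correlation. Igfbp2, encoding an insulin-like growth factor binding protein (-1.34 ± 0.17 and -1.36 ± 0.17), the protease inhibitor gene A2m (-1.68 ± 0.25 and -1.61 ± 0.24) and the nephronectin gene Npnt (-1.18 ± 0.16 and -1.19 ± 0.16) fell in both genotypes. So did Chst5 (-1.93 ± 0.26 and -1.67 ± 0.26) and Duoxa2 (-1.86 ± 0.27 and -1.57 ± 0.27). Further decreases were those of Duox2 (-1.91 ± 0.22), Wnt5a (-0.94 ± 0.13) and Myb (-1.13 ± 0.17) in wild type and Angptl7 (-1.52 ± 0.24), Matn4 (-1.09 ± 0.18) and Frem3 (-1.87 ± 0.33) in Efemp1ki/ki. The genotypes shared 342 of these genes in the same direction, 254 up and 88 down, where independent lists would share 12.8 and 5.49, and none in opposite directions. Lens genes fell in 10 of 11 cases in wild type, of which Crybb2 fell by 8.63 on the log2 scale. It went from 21.2 ± 49.2 CPM at 3 months to 0.0472 ± 0.0877 CPM at 17 months. Over the whole list there was adjusted p = 0.744 with an estimated correlation. On the log2(TPM + 1) scale 24.9% of 2002 genes were higher in wild type, against 46.4% of the 1059, and 40.4% of 732 in Efemp1ki/ki, against 72.9% of the 643, the median fold change of all genes there lying at -0.06 against 0.06.

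In the retina, ageing changed 3071 genes in wild type (1705 up, 1366 down) and 3233 in Efemp1ki/ki (1680 up, 1553 down), and values are paired in the same order. Glb1l3 (ENSMUSG00000031966.7, chromosome 9, 26817953 to 26860890), a beta-galactosidase-like gene, had the smallest p of the genes with an established name in both genotypes, with log2 fold changes of 1.02 ± 0.06 and 1.01 ± 0.06. The retinol dehydrogenase gene Rdh1 (2.70 ± 0.17 and 2.42 ± 0.16), the ubiquitin ligase gene Rnf43 (1.57 ± 0.10 and 1.70 ± 0.10) and the prokineticin gene Prok1 (1.52 ± 0.10 and 1.58 ± 0.10) rose in both. The same held for the calcitonin receptor gene Calcr (2.09 ± 0.16 and 2.22 ± 0.16), the muscle LIM protein gene Csrp3 (1.86 ± 0.13 and 1.79 ± 0.13), Fndc1 (1.02 ± 0.07 and 1.12 ± 0.07) and the histidine decarboxylase gene Hdc (0.76 ± 0.06 and 0.95 ± 0.06). Agtr1a, the angiotensin receptor gene (2.43 ± 0.26 and 2.66 ± 0.28), rose from under 1 CPM, Ly75 (1.63 ± 0.11) and Col4a4 (0.94 ± 0.07) led in wild type, and Tnxb (1.14 ± 0.09) in Efemp1ki/ki. Prdm1, a transcriptional repressor of photoreceptor development (-0.98 ± 0.09 and -1.04 ± 0.09), the kinetochore gene Spc25 (-0.87 ± 0.08 and -0.84 ± 0.08), Gulp1 (-0.99 ± 0.13 and -1.24 ± 0.13), Tmem26 (-1.62 ± 0.23 and -2.14 ± 0.24), Otop3 (-1.01 ± 0.14 and -1.10 ± 0.14) and Pcsk5 (-0.77 ± 0.10 and -0.72 ± 0.10) fell in both. Rorb, a nuclear receptor gene of retinal development, fell by 0.55 and Rspo2 by 1.89 on the log2 scale in wild type, and Nxnl2, encoding a rod-derived cone viability factor, by 0.59 in Efemp1ki/ki. Complement component genes rose in 7 of 12 cases in wild type and 10 in Efemp1ki/ki, 7 and 11 adjusted over the list alone (adjusted p = 0.0385 and 0.00153 with an estimated correlation). C4b changed by 1.03 ± 0.18 and 2.06 ± 0.17, C3 by 0.66 ± 0.21 and 1.71 ± 0.21, C1qa by 0.73 ± 0.11 and 0.97 ± 0.11 and C1s1 by 0.50 ± 0.15 and 1.00 ± 0.15. The regulators Serping1 (0.34 ± 0.11 and 0.70 ± 0.11) and Cd59a (0.21 ± 0.07 and 0.22 ± 0.07) rose in both, Cd46 rose (0.26 ± 0.09) and Cd55 fell (-0.79 ± 0.25) in wild type, and Cfb (0.24 ± 0.08) and Cfp (0.25 ± 0.09) rose in Efemp1ki/ki. Antigen presentation genes of MHC class I rose in 10 and 13 of 15 cases, 12 and 14 adjusted over the list alone, led by H2-K1 (0.66 ± 0.07 and 0.96 ± 0.07), a member of a gene family with shared reads, and the peptide transporter gene Tap2 (0.51 ± 0.08 and 0.78 ± 0.08; adjusted p = 0.177 and 0.00431 with an estimated correlation). Microglia and macrophage genes rose in 11 and 12 of 15 (12 and 13 adjusted over the list alone; adjusted p = 0.0385 and 0.00431 with an estimated correlation), including Lyz2 (1.82 ± 0.29 and 2.23 ± 0.28). Reactive glia genes rose in 8 and 11 of 16 (8 and 12 adjusted over the list alone; adjusted p = 0.311 and 0.00431 with an estimated correlation), including Edn2 (1.07 ± 0.18 and 1.5 ± 0.18) and Osmr (0.42 ± 0.07 and 0.67 ± 0.07). Of 27 interferon response genes 22 rose in Efemp1ki/ki, such as Ifi27 (1.17 ± 0.20) and Oas2 (1.29 ± 0.23), and 2 in wild type. Adjusted over the list alone 27 and 2 did (adjusted p = 0.191 and 0.725 with an estimated correlation). Wild-type library 6 at 3 months (2.99 log2 CPM, next 2.04) and library 5 at 17 months (2.97, next 2.41) lay apart in this list. Genes of retinal ganglion cells fell in 5 and 7 of 12 cases (8 in each genotype adjusted over the list alone; adjusted p = 0.311 and 0.133 with an estimated correlation), with Nefl at -0.27 ± 0.05 and -0.34 ± 0.05 and Pou4f1 at -0.27 ± 0.06 and -0.28 ± 0.06. Basement membrane genes rose in 8 of 21 in each genotype (10 and 9 adjusted over the list alone; adjusted p = 0.311 and 0.191 with an estimated correlation), Col4a3 by 1.22 ± 0.10 and 1.14 ± 0.10. The genotypes shared 1692 ageing genes in the same direction, 923 up and 769 down, where independent lists would share 166 and 123, and none in opposite directions. On the log2(TPM + 1) scale 83.5% of 3936 genes were higher in wild type, against 55.5% of the 3071, and 81.9% of 3490 in Efemp1ki/ki, against 52.0% of the 3233.

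**Figure D4:**
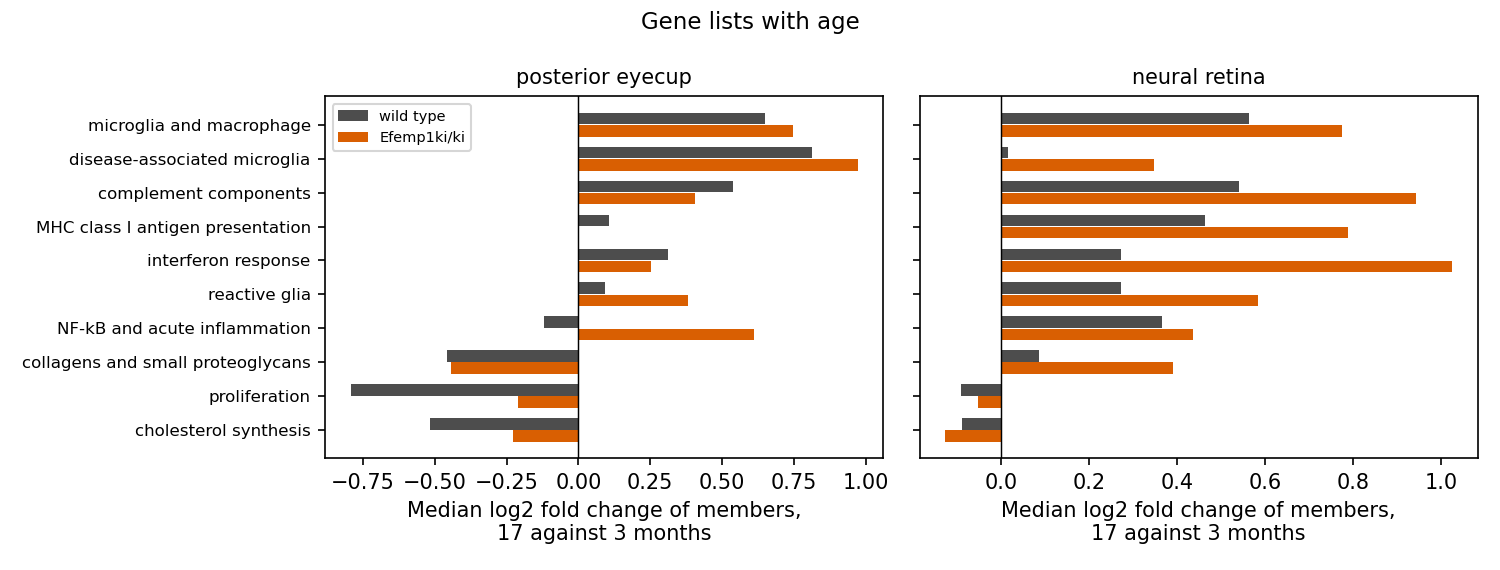
Median log2 fold change from 3 to 17 months of the members of 10 gene lists, in grey for wild type and orange for Efemp1ki/ki, in eyecup and retina. Microglia and macrophage genes have medians of 0.65 and 0.75 in eyecups, and interferon response genes 0.27 and 1.03 in retinas.

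Whether the genotype difference changed between 3 and 17 months was tested directly, and 0 genes passed in either tissue with edgeR. At an unadjusted p under 0.05 there were 560 genes in the eyecup and 690 in the retina, DESeq2 called 1 and 0, and limma voom with quality weights called 0 in both. In the eyecup the smallest p-values belonged to the neutrophil chemokine genes Cxcl5 (5.18 ± 1.01, adjusted p = 0.129), Cxcl1 (3.72 ± 0.83) and Cxcl2 (3.69 ± 0.88), to Klk13 (3.07 ± 0.67), Zc3h12a (1.45 ± 0.36), the cytokine genes Lif (1.38 ± 0.35) and Il1f6 (2.44 ± 0.64), Tnf (2.05 ± 0.54), Mab21l3 (2.05 ± 0.55) and Alb (8.45 ± 2.24), all with positive values. Wild-type library 6 at 3 months was highest for Cxcl1 (3.46 log2 CPM, next 0.58) and Cxcl5 (3.15, next 1.03). The NF-kB and acute inflammation list had a median of 0.64, 5 of 20 higher adjusted over the list alone and 0 over all genes. Camera adjusted p was 1.46e-08, and 0.593 with an estimated correlation. In the retina C4b had a difference of 1.03 ± 0.25, adjusted p = 1.00, and Oasl1 (2.25 ± 0.59), Trim34a (1.06 ± 0.28), Tap1 (0.80 ± 0.22), Irf1 (0.54 ± 0.15), Car4 (1.07 ± 0.29), Tmem81 (0.40 ± 0.11) and Cdh1 (1.29 ± 0.37) were among the 10 smallest p-values. Interferon response genes had a median of 0.64 and reactive glia genes one of 0.24. Camera adjusted p was 1.56e-12 and 6.32e-09, and 0.347 and 0.0598 with an estimated correlation. The wild-type libraries apart in interferon genes entered here too.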

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

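The tests of GC content, of libraries with extreme GC trends, of tissue composition, of immediate early gene means, of clock genes, of single libraries and of microglia were chosen after the results were seen. So were the splits for the genotype at 3 months in both tissues and at 9 months in the eyecup. The other splits were planned, and the fits with composition covariates had been planned as alternatives.

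At 3 months the eyecup calls leaned towards genes of low GC content. GC offsets brought the number of calls from 553 to 17, and the median log2 fold change of the 469 lower genes went from -0.56 to -0.22 (median SE 0.137 and 0.0986), so the calls ended because the fold changes shrank. Omitting Efemp1ki/ki libraries 3 and 4 left 14 genes, and the 468 lower genes still tested had a median of -0.39 (median SE 0.121), which decides little because they were chosen with the remaining libraries, whose GC trends still differed (0.0511 to 0.217 in Efemp1ki/ki, -0.103 to -0.0334 in wild type). Covariates for tissue composition kept all 553 and called 2150, but a smaller spread alone can raise counts, so composition stays open. GC offsets and these covariates together called 386, 196 higher and 190 lower, 133 of them among the 553. A GC-dependent difference between libraries may thus account for many calls, but how far stays open. So does its origin, in preparation or genotype, because the trend itself differed between genotypes. A genotype effect is left as a hypothesis for Plagl1, past the threshold in all 14 alternatives.

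Averaged over the ages, immediate early genes were higher in Efemp1ki/ki, by 0.433 log2 units in eyecups (95% interval 0.243 to 0.623). Retinas differed by 0.224 (0.116 to 0.332), with 0.356, 0.0832 and 0.233 at 3, 9 and 17 months. Age-stratified permutation gave p = 1e-05, the smallest possible, in eyecups and 0.00034 in retinas. Adjusted over 4 tests chosen on these data, p was 4e-05 and 0.00068. Per age, exact permutation gave adjusted p of 0.110 to 0.201 in eyecups and 0.110 to 0.681 in retinas (66 tests). The larger camera adjusted p of both tissues was 1.13e-04 with the GC trend removed and 3.32e-06 with composition covariates. Over 5 alternatives p was 1.87e-11 to 0.554 in the eyecup and 3.32e-06 to 0.484 in the retina. The highest used an estimated correlation, so GC and composition stay open. An index of clock genes, which would shift with the hour of collection, differed by 0.0191 in retinas (-0.0353 to 0.0735, permutation p = 0.499). In eyecups it differed by -0.102 (-0.275 to 0.0716, permutation p = 0.269). Averaged over the ages it can miss a shift at 1 age, so collection time stays open. Handling before RNA was taken could likewise induce these genes, which no label records, so a genotype effect stays an untested hypothesis.

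C4b and C3 were higher in Efemp1ki/ki retinas at 17 months. With GC offsets C4b kept an adjusted p = 2.15e-04 (3.64e-08 to 0.0226 over 14 alternatives), and in C4b 8 of 8 knock-in libraries exceeded the highest wild-type one, which argues against GC bias and against a few libraries as the cause for C4b. More microglia and macrophages would raise all of their markers, yet these had a median log2 fold change of 0.0632 (SE of 15 members 0.0399), below the bound of 0.584 set for them from the change in C4b, which argues against that cause. C3 passed in 7 of 14 alternatives only. Higher complement transcription in ageing Efemp1ki/ki retinas is therefore a hypothesis, found and tested on the same data, and how reads divide between C4b and C4a stays open.

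Whether chance could give such counts was tested with 40 splits, the real one included. No other split reached the real count for the genotype in eyecups at 3 months (553 genes, 97 in the highest other split), in retinas at 3 months (316 against 3), at 17 months (70 against 8) and as the age mean (903 against 1). The same held for ageing in eyecups (1059 against 1 in wild type, 643 against 177 in Efemp1ki/ki) and retinas (3071 against 796, 3233 against 432) and for the difference between tissues (620 against 8). The real split can at best be 1 of 40, so chance became less likely but was not excluded. Nor do splits tell genotype apart from a GC or composition difference between the groups. Other splits reached the real count for eyecups at 9 months (1 against 1, 2 of the splits reaching it, the real one included), at 17 months (11 against 5341, with 4) and as the age mean (807 against 2257, with 2). For the 0 genes by edgeR of the retina at 9 months and of the change with age in either tissue, splits say nothing about chance, since any split reaches 0, and the highest others were 0, 0 in the retina and 2574 in the eyecup. Their counts at an unadjusted p under 0.05 were 1047, 690 and 560, and DESeq2 called 0, 0 and 1. Why some splits of the eyecup libraries called far more genes than the real one was not tested.

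Tested directly, genotype differences differed between tissues in 620 genes. From 3 to 17 months the genotype difference of 13 gene lists changed in the retina, led by interferon response (camera adjusted p = 1.56e-12) and MHC class I antigen presentation (2.35e-09), and of 12 in the eyecup, led by proliferation genes (4.22e-10), with 0 of them past the threshold with an estimated correlation.

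In 76 of 848 groups tested, 1 library lay apart from the others, where chance marks about 1 in 20 groups. Each number in parentheses is the gap to the nearest library divided by the range of the group. Lens genes stood highest, as a list mean or singly, in wild-type retina library 2 at 3 months (list 0.871, Cryaa 0.775, Crybb2 0.832, Crygs 0.820), Efemp1ki/ki retina library 8 at 17 months (list 0.597, Cryba1 0.770, Cryba2 0.720, Crybb2 0.561), wild-type retina library 4 at 9 months (list 0.716, Cryba1 0.776, Cryba2 0.692, Crybb2 0.565, Crygs 0.726), Efemp1ki/ki retina library 6 at 9 months (list 0.598, Cryba2 0.561) and Efemp1ki/ki eyecup library 6 at 17 months (list 0.571). The mean of the interferon response list was highest in Efemp1ki/ki eyecup library 7 at 9 months (0.686), Efemp1ki/ki retina library 7 at 3 months (0.679), wild-type retina library 5 at 17 months (0.664) and wild-type retina library 6 at 3 months (0.850). Library totals were highest in Efemp1ki/ki eyecup library 4 at 17 months (0.712), wild-type eyecup library 4 at 17 months (0.600) and wild-type retina library 1 at 17 months (0.588). Among immediate early genes, Atf3 (0.695) and the list mean (0.616) were highest in Efemp1ki/ki eyecup library 5 at 17 months. Fos was lowest in wild-type retina library 4 at 9 months (0.591). Fosb was highest in Efemp1ki/ki eyecup library 8 at 3 months (0.557). Efemp1ki/ki retina library 5 at 3 months was lowest in GC trend (0.694), Otop3 (0.808) and Tap2 (0.605). It was highest in Glb1l3 (0.547) and Spc25 (0.547). Wild-type eyecup library 3 at 3 months was highest in Ctsb (0.679), Ctsz (0.750), Cybb (0.670), Itgb2 (0.696), Lyz2 (0.670) and Papln (0.635). It was lowest in Slc18a2 (0.737). Efemp1 itself was lowest in Efemp1ki/ki eyecup library 4 at 3 months (0.682), at 7.11 against 7.80 log2 CPM in the next library. C1qa was lowest in Efemp1ki/ki eyecup library 9 (0.603) and wild-type retina library 7 (0.638), both at 3 months. C1qa (0.581) and C2 (0.531) were lowest in wild-type eyecup library 2 at 17 months. Further eyecup genes that were highest in 1 library were Cxcl1 (0.720) and Cxcl5 (0.652) in wild-type library 6 at 3 months, Clec7a (0.595) and Eif4a-ps4 (0.645) in Efemp1ki/ki library 2 at 17 months, Hopxos (0.664) in Efemp1ki/ki library 1 at 3 months, C5ar1 (0.735) and Col12a1 (0.580) in Efemp1ki/ki library 8 at 3 months, Lrat (0.566) in Efemp1ki/ki library 3 at 9 months, and Kprp (0.730) in Efemp1ki/ki library 7 at 9 months. Further eyecup genes that were lowest in 1 library were Hyou1 (0.534) in wild-type library 8 at 17 months, Cldn34c1 (0.700) and Zfp968 (0.851) in wild-type library 2 at 3 months, Slc24a5 (0.571) in wild-type library 5 at 9 months, Cldn34c1 (0.577) in Efemp1ki/ki library 1 at 17 months, A2m (0.591) and Matn4 (0.655) in Efemp1ki/ki library 7 at 17 months, and Znf41-ps (0.594) in Efemp1ki/ki library 3 at 3 months. Further retina genes that were highest in 1 library were Csrp3 (0.541) in wild-type library 2 at 17 months, Trim34a (0.535) in wild-type library 6 at 3 months, Cdh1 (0.592) and Itgax (0.554) in wild-type library 7 at 3 months, Rdh1 (0.528) in Efemp1ki/ki library 3 at 17 months, Col4a4 (0.530) and Tap1 (0.550) in Efemp1ki/ki library 5 at 17 months, and Thy1 (0.582) in Efemp1ki/ki library 7 at 9 months. Further retina genes that were lowest in 1 library were Spc25 (0.619) in wild-type library 2 at 17 months, Col4a5 (0.543) in wild-type library 4 at 3 months, Nrl (0.554) in wild-type library 7 at 3 months, Agrn (0.587) in Efemp1ki/ki library 6 at 17 months, Fut4 (0.586) in Efemp1ki/ki library 3 at 3 months, Lyz2 (0.564) in Efemp1ki/ki library 4 at 3 months, and Rbpms (0.593) in Efemp1ki/ki library 2 at 9 months.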

How the results depend on the processing

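Settings with GC in their name, alone or combined, were chosen after the data were seen, and the other settings were planned. The count of called genes in each comparison was recomputed under 14 settings, and 108 of 210 counts, list tests included, lay within 1.5 times the reported count. Where they did not, the cause was not tested. Named genes were recomputed too. Of their results 4439 kept direction and side of the threshold, 549 kept direction and no longer passed, 20 newly passed and 47 changed sign, most of them Efemp1 or Cfb values near 0. All 15 counts stayed within 1.5 times with RLE size factors in edgeR.

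Genes passing in the comparisons that moved were as follows. Without the low-count filter counts moved to 5 (17 months) in the eyecup, 121 (3 months), 3 (17 months) and 562 (the age mean) in the retina, and 299 for the difference between tissues. With covariates for cell composition they were 2150 (3 months), 0 (9 months), 17 (17 months), 1876 (the age mean) and 355 (wild-type ageing) in the eyecup, 0 (3 months), 15 (17 months), 252 (the age mean), 1625 (wild-type ageing) and 1840 (Efemp1ki/ki ageing) in the retina, and 313 for the difference between tissues. Surrogate variables gave 0 (9 months), 728 (17 months), 2161 (the age mean), 1980 (wild-type ageing) and 2071 (Efemp1ki/ki ageing) in the eyecup, 23 (3 months), 2 (9 months), 4 (17 months), 13 (the age mean), 1408 (wild-type ageing) and 864 (Efemp1ki/ki ageing) in the retina, and 1563 for the difference between tissues. Leaving out the libraries that stood apart gave 3 (17 months) in the eyecup, 536 (3 months) and 1 (17 months) in the retina, and 352 for the difference between tissues. Fits of only the 2 groups compared, with fewer libraries behind the spread, gave 101 (3 months), 0 (9 months), 0 (17 months) and 304 (Efemp1ki/ki ageing) in the eyecup, and 557 (3 months) and 1 (17 months) in the retina. limma voom with quality weights called 2359 (3 months), 0 (9 months), 478 (17 months), 1585 (the age mean), 2622 (wild-type ageing) and 2286 (Efemp1ki/ki ageing) in the eyecup, and 1927 (3 months), 1 (17 months), 1844 (the age mean) and 4721 (wild-type ageing) in the retina. limma on log2(TPM + 1) called 10 (3 months), 0 (9 months), 0 (17 months), 34 (the age mean) and 2002 (wild-type ageing) in the eyecup, 648 (3 months), 682 (17 months) and 2008 (the age mean) in the retina, and 25 for the difference between tissues. DESeq2 called 976 (3 months), 0 (9 months), 52 (17 months), 1257 (the age mean), 1726 (wild-type ageing), 1017 (Efemp1ki/ki ageing) and 1 (the change with age) in the eyecup, 594 (3 months) and 272 (17 months) in the retina, and 1101 for the difference between tissues. Counts of 0 here came from edgeR unless limma or DESeq2 is named, and the report gives those comparisons' counts at an unadjusted p under 0.05.

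With GC offsets counts were 17 (3 months), 0 (17 months) and 153 (the age mean) in the eyecup, 591 (3 months), 385 (17 months) and 1865 (the age mean) in the retina, and 51 for the difference between tissues. GC offsets with the composition covariates gave 0 (9 months), 76 (17 months) and 425 (wild-type ageing) in the eyecup, 9 (3 months), 141 (17 months), 1824 (wild-type ageing) and 2013 (Efemp1ki/ki ageing) in the retina, and 71 for the difference between tissues. Without the libraries of extreme GC trend there were 14 (3 months), 534 (the age mean) and 299 (Efemp1ki/ki ageing) in the eyecup, 726 (3 months) and 1 (17 months) in the retina, and 96 for the difference between tissues.

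Within a tissue and age, the replicate numbers shared between genotypes were not shown to pair the libraries, since in no combination did every pair correlate over 0.1, but shared origin is not ruled out either, with 4 of 7 pairs over 0.1 in eyecups at 9 months. Same-numbered libraries correlated in their deviations from the group mean with medians from -0.215 to 0.288 over the 6 tissue and age combinations, and the libraries that correlated best with their own number were 3 of 8 in eyecups at 9 months, 7 of which had a shared number, 1 of 8 in retinas at 3 months and 0 in the other 4 combinations. Between the tissues of a genotype and age, same-numbered libraries had median correlations from -0.0245 to 0.150, highest in Efemp1ki/ki at 3 months (5 of 7 pairs over 0.1), and here too no combination had every pair over 0.1, so a shared mouse was neither shown nor ruled out. With the replicate number as a block, counts were 160 (3 months), 1 (17 months) and 398 (wild-type ageing) in the eyecup, and 347 for the difference between tissues, and with GC offsets and the block 3 (3 months), 0 (17 months), 106 (the age mean), 461 (wild-type ageing) and 414 (Efemp1ki/ki ageing) in the eyecup, 637 (3 months), 392 (17 months) and 1916 (the age mean) in the retina, and 46 for the difference between tissues. The block changed no other count by over 1.5 times.

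Log2 fold changes took the sign opposite to the reported ones as follows. With GC offsets, Efemp1 and Cfb were at 0.0048 and -0.0321 in eyecups at 3 months. Efemp1 was at -0.0254 for the change with age there. Between tissues Efemp1 was at 0.0076 and Prpf38b at 0.0623. With GC offsets and composition covariates, Efemp1 was at 0.0125 in eyecups at 3 months and 0.0219 for ageing wild-type retinas. For the change with age in eyecups Efemp1 was at -0.19 and Cfb at -0.0243. Between tissues Cfb was at -0.0108 and Prpf38b at 0.0044. Pdc was at 0.0433 for ageing Efemp1ki/ki retinas. With GC offsets and the replicate block, eyecup Efemp1 was at 0.0473 at 3 months, 0.0129 at 9 and 0.0135 for the age mean. For the change with age there it was at -0.0672. Between tissues Efemp1 was at 0.0291 and Prpf38b at 0.0456. With surrogate variables, Efemp1 was at 0.0281 in eyecups at 3 months, -0.13 for their change with age and 0.0999 for ageing wild-type retinas. It was at 0.0693 in retinas at 3 months, 0.0073 for their age mean, -0.0335 for their change with age and 0.0231 between tissues. Cfb was at -0.0700 for the change with age in eyecups and Cfp at -0.0220 for ageing Efemp1ki/ki retinas. For the age mean in retinas Cryaa and Cryba2 were at -0.19 and Cryba1 at -0.0828. With composition covariates alone, Cfb and Efemp1 were at -0.0535 and -0.0874 for the change with age in eyecups. Efemp1 was at 0.0059 in retinas at 3 months. With the block alone, Efemp1 was at 0.0047 in eyecups at 9 months. With libraries of extreme GC trend left out, Efemp1 was at -0.0650 for the change with age in eyecups and 0.0093 for the age mean in retinas. With limma voom, Efemp1 was at 0.0276 in eyecups at 3 months and -0.0535 for the change with age in eyecups. With limma on log2(TPM + 1), eyecup Cbx3 was at 0.0273 and Efemp1 at 0.0230 at 3 months, and Igip at 0.11 as age mean. Efemp1 was at 0.0034 in eyecups at 9 months, -0.0565 for their change with age and 0.0222 for the age mean in retinas. For the age mean in retinas Efemp1 was also at 0.0036 with RLE size factors, at 0.0030 without the low-count filter and at 0.0022 with DESeq2. The cause was not tested.

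Other scalings moved the share of higher genes. DESeq2 gave 27.5% in eyecups at 3 months against 15.2% as reported, 53.8% at 17 months against 72.7%, 62.7% for ageing Efemp1ki/ki eyecups against 72.9% and 52.1% for the difference between tissues against 25.3%. GC offsets gave 41.2% in eyecups at 3 months, 39.9% for the age mean in eyecups against 24.9% and 41.0% for ageing Efemp1ki/ki retinas against 52.0%.

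Of 91 list results past the threshold with the preset correlation over the 8 genotype comparisons, 0 passed with camera's estimated correlation, while 72 lists passed with composition covariates, 92 with the replicate block, 90 with the GC trend removed and 93 without libraries of extreme GC trend. The direction of a list's test opposed the sign of its median in 2 cases, rod photoreceptor (0.06) and amacrine cell genes (0.04) of ageing Efemp1ki/ki eyecups, both tested as lower than other genes. Depth limits genes under 1 CPM, which rest on about 9 reads or fewer in the smallest library of 9218127 counts.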

Other observations

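Between 3 and 17 months some genes of protein synthesis, respiration and phototransduction fell in the retina by small amounts, given for wild type and then Efemp1ki/ki. Of 43 cytosolic ribosomal protein genes, many of which have processed copies with uncertain reads, 18 and 14 fell, 25 and 21 adjusted over the list alone, with Rps14 at -0.23 ± 0.06 and -0.22 ± 0.06 and Rpl19 at -0.19 ± 0.05 and -0.18 ± 0.05 (adjusted p = 0.405 and 0.388 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 10 and 8 of 41 cases, 11 and 10 adjusted over the list alone, with the ATP synthase gene Atp5c1 at -0.17 ± 0.05 and -0.19 ± 0.05 and Uqcrc2, of respiratory complex III, at -0.15 ± 0.04 and -0.16 ± 0.04 (adjusted p = 0.468 and 0.442 with an estimated correlation). Rod genes fell in 5 and 4 of 19 cases while 1 rose in Efemp1ki/ki, and adjusted over the list alone 12 and 6 fell and 1 rose in each genotype. Among them were phosducin, Pdc (-0.34 ± 0.06 and -0.28 ± 0.06), and the rod transcription factor gene Nrl (-0.19 ± 0.04 and -0.15 ± 0.04; adjusted p = 0.468 and 0.490 with an estimated correlation). For cones the counts were 6 and 5 of 13 lower with 2 higher in Efemp1ki/ki, and 7 and 5 lower with 1 and 2 higher adjusted over the list alone, including the phosphodiesterase gene Pde6h (-0.30 ± 0.05 and -0.20 ± 0.05; adjusted p = 0.311 and 0.428 with an estimated correlation). NF-kB and acute inflammation genes rose in 5 and 6 of 12 cases, 6 and 7 adjusted over the list alone, with the adhesion molecule gene Icam1 at 1.07 ± 0.16 and 1.46 ± 0.16 (adjusted p = 0.298 and 0.0164 with an estimated correlation), and complement receptors in 3 and 2 of 4, 3 in each genotype adjusted over the list alone, with Itgax at 1.09 ± 0.36 and 1.81 ± 0.37 (adjusted p = 0.361 and 0.157 with an estimated correlation).

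In ageing eyecups, again in the order wild type, Efemp1ki/ki, disease-associated microglia genes rose in 5 of 11 cases each, 6 and 7 adjusted over the list alone, with osteopontin, Spp1, at 1.36 ± 0.20 and 1.49 ± 0.19 (adjusted p = 0.307 and 0.0338 with an estimated correlation). Complement receptor genes rose in 4 of 9 cases each, such as the anaphylatoxin receptor genes C3ar1 (1.38 ± 0.24 and 1.43 ± 0.22) and C5ar1 (1.01 ± 0.25 and 0.95 ± 0.23), and adjusted over the list alone 4 rose in each genotype and 2 fell in wild type (adjusted p = 0.521 and 0.245 with an estimated correlation). Lysosome genes rose in 7 and 4 of 22 cases, 8 and 5 adjusted over the list alone, with the cathepsin genes Ctsz (0.68 ± 0.13 and 0.63 ± 0.12) and Ctsb (0.48 ± 0.11 and 0.45 ± 0.11; adjusted p = 0.613 and 0.600 with an estimated correlation). B and plasma cell genes rose in 3 of 7 cases each, with the immunoglobulin joining chain gene Jchain at 2.29 ± 0.48 and 2.59 ± 0.44, and adjusted over the list alone 3 and 4 rose and 3 fell in wild type (adjusted p = 0.766 and 0.456 with an estimated correlation). The NF-kB list split in wild type, 2 members rising and 3 falling of 20, whereas 7 rose in Efemp1ki/ki, among them the chemokine gene Ccl2 (1.98 ± 0.41). Adjusted over the list alone these counts were 2, 4 and 9, and for the difference between genotypes the list had camera adjusted p = 1.46e-08 and adjusted p = 0.593 with an estimated correlation (within each genotype adjusted p = 0.989 and 0.327 with an estimated correlation). Skeletal muscle genes had medians of 1.11 and 0.86 over 23 members without any past the threshold (adjusted p = 0.744 and 0.679 with an estimated correlation).

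A knock-in line can keep sequence of the donor strain around the targeted gene, which could make genes near Efemp1 differ without any action of fibulin-3. The test was fixed before its result was seen. Within 20 Mb of Efemp1 on chromosome 11, 10 of 164 eyecup genes differed as the mean of the ages (6.10%, against 4.47% elsewhere; odds ratio 1.39, 95% interval 0.650 to 2.64, Fisher's exact p = 0.338). In the retina 6 of 156 did (3.85%, against 5.25%; odds ratio 0.722, 0.260 to 1.61, Fisher's exact p = 0.586). Neither interval excludes a moderate excess, so for the few called genes in that window a strain variant cannot be told apart from the knock-in.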
